A study of Homo sapiens with 96 samples.

How the data were processed

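The series measured RNA in hTERT-RPE1 cells, an established line of human retinal pigment epithelium made immortal with telomerase, by sequencing. Of its 96 samples, 91 had columns in the expression tables and were used. The other 5 are chromatin samples (4 histone marks and an input) and were not analysed here. Per the labels' protocols, cells were synchronised with 400 uM mimosine, an iron chelator that holds cells before S phase, for 22 h, and knockdown cells were transfected with 130 to 150 pmol of LNA GapmeRs, antisense oligonucleotides that direct RNase H to an RNA. The labels name windows T0-2, T2-4, T4-6, T6-8 and T8-10 and points S0, S2, S4 and S6; the unit of these numbers is not given in the sources used here.

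The authors deposited 10 tables with 1 column per library. Per the file headers, 4 tables hold nascent or input RNA of whole cells or nuclei, 3 hold control and knockdown libraries of synchronised cells, and 3 hold those of asynchronous cells. The values of these columns are RPKM (reads per kilobase of gene, scaled to library size) as the authors deposited them. STAR 2.5.3, featureCounts 1.6.1, edgeR (version not given in the sources used here) and HOMER 4.10.3 on hg38 are named for all 96 samples in the submitters' processing notes, which state no order or role. Bowtie2 2.3.4.3 is named for 85 of them in the same notes. The annotation, any filter on genes, and whether RNA was selected by poly(A) tails are not given in the sources used here. The knockdown libraries were strand-specific per the series' design text. For the fraction tables strand use in counting is not stated, so reads of overlapping genes such as MIAT and MIATNB, or LINC00704 and LINC00705, may not be separable there. Histone genes, pseudogenes and snRNA genes have near-identical copies, so their single values are uncertain.

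The 3 asynchronous tables also hold the authors' own comparison. Per the file headers, these are a log2 fold change, a p-value and an FDR per gene, by a test that the headers do not name. The log2 fold change equals the log2 ratio of the authors' deposited group means, each with 0.1 added. A gene length column, in base pairs per the file headers, was used as deposited and gave lengths to the other tables. The tables were scaled separately, so tests were run only within a table. LINC00704 is named MANCR in the files, and LINC00704 is used here for the targeted RNA.

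For genes with a known length, multiplying RPKM by it gave whole multiples of 1 step per library for at least 99.9% of the values checked (counts up to 200, tolerance 0.05 of a read), so reads per library were recovered from the steps. They ran from 6.39 to 23.6 M in whole-cell nascent, 7.84 to 23.4 in whole-cell input, 12.5 to 28.6 in nuclear nascent and 8.33 to 19.6 in nuclear input RNA. Synchronised libraries of the LINC00704, LUCAT1 and MIAT tables had 11.7 to 23.4, 9.11 to 20.9 and 12.1 to 20.9 M, and asynchronous ones 27.3 to 42.1, 26.4 to 42.2 and 27.3 to 50.5 M. The library size behind the steps was 1.00 to 1.06 times the recovered reads in the fraction and synchronised tables and 0.892 to 1.17 times in the asynchronous ones, so the latter carry a further factor per library. The deepest libraries are asynchronous knockdowns, and the shallowest are the 2 asynchronous whole-cell nascent ones.

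The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.25), for genes with at least 0.5 RPKM in at least 2 libraries of a table, with a mean trend in eBayes and Benjamini-Hochberg adjustment; genes under an adjusted p of 0.05 were called. All log2 differences below are on this scale, which understates changes of weak genes. The windows were compared as the mean of 5 window means against asynchronous cells (10 against 2 libraries), and knockdowns as the mean over 4 points of knockdown minus control (8 against 8) or, in asynchronous cells, as 3 against 2 libraries. Differences among windows, among control points, and of knockdown effects among points were tested with moderated F-tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Tables and tests, the 22 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The contrasts T8-10 against T0-2 and S6 against S0 were chosen after.

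Of the 22 lists, 18 were tested with camera (preset correlation 0.01, at least 5 tested members): histones, G1/S genes, G2/M genes, p53 targets, immediate early genes, interferon-stimulated genes, NF-kB and cytokine genes, hypoxia and iron genes, ATF4 and unfolded protein response genes, NRF2 targets, extracellular matrix genes, sterol genes, ribosomal protein genes, mitochondrially encoded genes, snoRNA host genes, nuclear lncRNAs, markers of other cell types, and pigment epithelium genes. The targets and the neighbours of each target make up the other 4. No mitochondrially encoded gene was in the tested set of any table, and the markers of other cell types had at most 3 tested members, too few for camera.

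Named genes followed a rule. It took the targets and their neighbours, and the 10 largest rises and falls among called genes with a symbol that is no clone name and a mean of at least 1 RPKM on the higher side (for knockdowns, with every library separated at each point). From lists whose camera test passed or that held at least 5 called genes it took up to 4 called members, and from lists without calls the 2 members with the highest RPKM. It also took up to 10 risen and 5 fallen lncRNAs in whole-cell nascent RNA. Fewer may be named, in rank order. Coordinates of targets and neighbours came from a RefSeq table of GRCh38.p14, the build the notes name.

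Alternatives were pseudocounts of 1 and 0.1, no filter, at least 1 RPKM, median scaling, quantile normalization, no mean trend, a replicate block, each library left out, and camera with an estimated correlation. After the data were seen, limma-voom on recovered reads, removal of a gene-length trend, a block over window libraries alone, and runs without doubted libraries were added. Same-numbered libraries deviated together in nuclear input RNA (correlation across genes 0.63 to 0.86 over all 15 pairs of groups), so its blocked values stand beside the main ones. In whole-cell nascent and input RNA this held among windows only (0.29 to 0.59 and 0.88 to 0.94 over 10 pairs), with -0.27 to 0.17 and -0.56 to -0.47 between asynchronous cells and windows. Comparisons with shared controls were set beside 50 simulations of unchanged groups. Values of some genes that the naming rule picked are not reported here.

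The tests were run on simulated data with known changes. At a 2-fold change 51.6% of 95 changed genes were recovered for windows in whole-cell nascent RNA, 86.0% of 93 in nuclear input RNA, 98.9% of 93 for synchronised LUCAT1 knockdown, 100% of 96 for asynchronous MIAT knockdown and 43.3% of 97 for differences among windows in nuclear input RNA. At 4-fold, 100% were recovered in each (91, 90, 95, 96 and 98 genes). False calls made up 9.09%, 11.9%, 5.56%, 11.1% and 7.28% of all calls, and no recovered gene had the wrong sign in the first 4. A G2/M list of 46 genes raised 1.5-fold in the simulated LUCAT1 comparison was called by camera (adjusted p = 3.8e-87, and adjusted p = 1.3e-07 with an estimated correlation), with 0 of 14 other lists called. Each gene was drawn independently, so the simulations hold no correlation between genes. They cannot show how often camera calls a list falsely where genes vary together.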

Results

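The title of the series names non-coding RNAs enriched in S phase. RNA was therefore measured in cells released into S phase and in asynchronous cells, and then after knockdown of LINC00704, LUCAT1 or MIAT. Nascent RNA and input RNA were each sequenced from whole cells and from nuclei, in asynchronous cells and in 5 windows, with 2 libraries per group (12 per table). Knockdown and control libraries of synchronised cells were taken at 4 points (2 libraries each, 16 per table), and asynchronous cells gave 2 control and 3 libraries per knockdown. Depth ran from 6.39 M recovered reads in a whole-cell nascent library to 50.5 M in an asynchronous MIAT knockdown library. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

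In whole-cell nascent RNA, the windows were compared with asynchronous cells to find transcripts made more or less in S phase. Every window library came from cells treated with mimosine, which is named for no asynchronous library. S phase and the drug block therefore cannot be told apart in this comparison, here or in the other kinds of RNA. TXNIP, an inhibitor of thioredoxin, was higher in the windows by 3.39 ± 0.45 (log2, SE; 10 and 2 libraries; limma adjusted p = 0.025), at 144 against 15.9 RPKM. RRM2B, a p53-induced subunit of ribonucleotide reductase, was higher by 2.21 ± 0.30, at 6.35 against 1.15 RPKM. SAT1, which acetylates polyamines, was higher by 1.89 ± 0.27 and the mitophagy receptor BNIP3L by 1.56 ± 0.27. NOG, a BMP antagonist, was listed at 0 in both asynchronous libraries and at a mean of 1.86 RPKM in the windows. PLK1, a mitotic kinase, was lower by 1.66 ± 0.27 (a log2 change of -1.66, 2.79 against 8.94 RPKM).

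Among long non-coding RNAs, AL590004.3 rose by 2.05 ± 0.28 in whole-cell nascent RNA, LINC01629 by 2.01 ± 0.32, AL021807.1 by 2.01 ± 0.35 and LINC02535 by 1.75 ± 0.30, while AC133540.1 changed by -2.53 ± 0.41 and AC019118.1 by -2.06 ± 0.34. Of 10096 genes, 25 rose and 16 fell (1387 at an unadjusted p under 0.05), and the fallen ones with the largest changes were weak pseudogenes such as NANOGNBP3 (-3.19 ± 0.31) and OR5B10P (-2.75 ± 0.34). Among lncRNAs 0.751% of 932 rose, against 0.184% of 8678 coding genes (Fisher's exact test, adjusted p = 0.016 over 20 such tests). Such tests count genes as independent, so their p-values do not measure the spread between libraries. In the windows, lncRNAs were not matched to coding genes on RPKM and length. With quantile normalization 44 rose and 50 fell, and with median scaling 24 and 25. The handling of weak genes also moved the split: 20 rose and 47 fell with a pseudocount of 1, 18 and 2 with 0.1, 21 and 51 with no filter, and 18 and 3 with RPKM of at least 1. Without asynchronous replicate 1 only 3 genes passed, the lowest count on leaving out a library, and without replicate 2 of T6-8 there were 27, the highest.

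Of 25 measured p53 targets in whole-cell nascent RNA, 1 rose over all genes and 15 rose adjusted over the list alone, with a median of 0.86 (camera adjusted p = 5.5e-13, but adjusted p = 0.22 with an estimated correlation). Hypoxia and iron genes had 1 of 29 risen (8 adjusted over the list alone; median 0.44, adjusted p = 8.3e-07, but adjusted p = 0.22 with an estimated correlation). Lists without a called gene also passed camera: NF-kB and cytokine genes (median 0.55, adjusted p = 8.4e-05), ATF4 and unfolded protein response genes (0.36, 0.0014), extracellular matrix genes (0.20, 0.0068) and interferon genes (0.28, 0.0080) upward, snoRNA hosts (-0.42, 8.9e-04) downward. With an estimated correlation each of these 5 had adjusted p = 0.22. Adjusted over the list alone, 5 of 21, 5 of 29, 2 of 21, 1 of 17 and 0 of 14 members rose. G2/M genes (median -0.21, adjusted p = 6.2e-04) had PLK1 as their 1 fallen member of 46, and adjusted p = 0.59 with an estimated correlation. The histone median of 0.80 (0 of 49 passed; adjusted p = 8.3e-07, but 0.52 as adjusted p with an estimated correlation) was -0.35 among libraries numbered 1 and 2.05 among those numbered 2. Ribosomal protein genes had a median of -0.26 (0 of 62 passed; adjusted p = 4.2e-05, and adjusted p = 0.52 with an estimated correlation), with -0.57 among libraries numbered 1 and -0.0069 among those numbered 2. Interferon genes had 0.013 and 0.43.

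Whole-cell input RNA, the steady-state pool, gave 3 called genes of 9825, all higher in the windows (865 at an unadjusted p under 0.05). CA9, a carbonic anhydrase induced by hypoxia, was higher by 4.91 ± 0.48 (18.1 against 0.333 RPKM; limma adjusted p = 0.020). NDRG1, induced by hypoxia and by iron chelators, was higher by 3.25 ± 0.29, and THSD1 by 1.70 ± 0.17. These 2 hypoxia genes were the risen members of 29 (4 adjusted over the list alone; median 0.83), and the list passed camera with adjusted p = 9.8e-17 and also with an estimated correlation, adjusted p = 0.012. The p53 targets had 0 of 24 called and 8 risen adjusted over the list alone (median 1.06, adjusted p = 9.2e-17, and adjusted p = 0.027 with an estimated correlation). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, had a difference of 2.30 ± 0.43 that did not pass (adjusted p = 0.13). Without asynchronous replicate 1 no gene passed, and quantile normalization gave 5 risen and 1 fallen. Histones had a median of 0.78 (1 of 46 risen adjusted over the list alone), with 1.61 among libraries numbered 1 and -0.22 among those numbered 2. Interferon genes also differed in sign, with 0.47 and -0.05. Histones had adjusted p = 0.52 with an estimated correlation, as had ribosomal protein genes (median -0.54) and G2/M genes (-0.50). Ribosomal protein genes had -0.054 among libraries numbered 1 and -1.11 among those numbered 2, and G2/M genes had -0.0056 and -1.17. SnoRNA hosts, with 6 of 14 fallen adjusted over the list alone, had a median of -1.07 (adjusted p = 1.0e-08, but adjusted p = 0.095 with an estimated correlation). Immediate early genes (median -0.46, 5 of 24 fallen adjusted over the list alone) had adjusted p = 0.0013 and adjusted p = 0.19 with an estimated correlation, and interferon genes (0.40, 0 of 17) adjusted p = 4.8e-04 and adjusted p = 0.21 with an estimated correlation.

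Nuclear nascent RNA gave 440 called genes of 9784, 191 higher and 249 lower in the windows. The p53 targets CDKN1A (2.38 ± 0.37, 36.2 against 6.18 RPKM), MDM2, the ubiquitin ligase of p53 (2.20 ± 0.22), and BTG2 (2.09 ± 0.22), with FDXR (1.72 ± 0.37), were among 13 of 26 that rose. Adjusted over the list alone 21 rose and 1 fell (median 0.99; camera adjusted p = 7.1e-17, and adjusted p = 0.026 with an estimated correlation). CA9 (3.46 ± 0.40), NDRG1 (2.83 ± 0.26), the glycolytic enzymes PGK1 (1.58 ± 0.26) and PFKFB4 (1.28 ± 0.22) were among 7 of 27 hypoxia and iron genes that rose (11 adjusted over the list alone; median 0.67, adjusted p = 6.5e-11, but adjusted p = 0.17 with an estimated correlation). The lncRNAs LINC01705 (3.06 ± 0.16; 3.09 against 0.0740 RPKM, adjusted p = 7.1e-05) and PURPL, a p53-induced lncRNA (2.77 ± 0.16), also rose, with TXNIP (2.23 ± 0.33) and SAT1 (2.13 ± 0.35). LncRNAs rose more often than coding genes, 4.32% of 787 against 1.70% of 8683 (Fisher's exact test, adjusted p = 3.7e-05). This test too counts genes as independent, without matching on RPKM and length, and the calls rest on 2 asynchronous libraries.

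In nuclear nascent RNA KIF20A, a mitotic kinesin (-2.37 ± 0.21, 5.27 against 27.4 RPKM), CDC20 (-2.32 ± 0.21), cyclin B1 gene CCNB1 (-1.89 ± 0.18) and PLK1 (-1.50 ± 0.22) were among 12 of 45 G2/M genes that fell (17 fell and 1 rose adjusted over the list alone; median -0.37, adjusted p = 7.9e-07, but adjusted p = 0.23 with an estimated correlation). MCM6 (-1.71 ± 0.16), MCM3 (-1.29 ± 0.20) and MCM5 (-1.09 ± 0.23), subunits of the replicative helicase, and UNG (-1.19 ± 0.20) were among 5 of 47 G1/S genes that fell, while 1 rose (10 and 1 adjusted over the list alone; median -0.10, adjusted p = 0.018, but adjusted p = 0.38 with an estimated correlation). Ribosomal protein genes had 22 of 63 fallen and 56 adjusted over the list alone, RPL4 by -1.54 ± 0.25 and RPL13A by -1.53 ± 0.29 (median -1.03, adjusted p = 8.0e-27, but adjusted p = 0.17 with an estimated correlation). Of the snoRNA hosts GAS5 (-1.61 ± 0.32) and ZFAS1 (-1.34 ± 0.27) fell, with 9 of 14 adjusted over the list alone (adjusted p = 3.4e-06, but adjusted p = 0.23 with an estimated correlation), as did the nucleolar genes NPM3 (-1.93 ± 0.38) and NOLC1 (-1.74 ± 0.25). SAMD9L (1.12 ± 0.18) was the 1 risen interferon gene of 17 (adjusted p = 0.0075, but adjusted p = 0.15 with an estimated correlation), and PTGS2 (1.36 ± 0.27) and TNFAIP3 (1.13 ± 0.21) the 2 of 19 NF-kB and cytokine genes (adjusted p = 0.0073, but adjusted p = 0.23 with an estimated correlation; 3 and 4 rose adjusted over the lists alone). Histones had a median of 0.26 with 0 of 46 called (adjusted p = 0.018, but adjusted p = 0.68 with an estimated correlation). Counts per window were 330 at T0-2, 195 at T2-4, 122 at T4-6, 56 at T6-8 and 26 at T8-10. T8-10 replicate 2 (first principal component -50.4, others -14.4 to 40.9) leaves the last uncertain. Without asynchronous replicate 2 few genes passed for the window mean, and quantile normalization gave 123 risen of 229 called.

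Nuclear input RNA gave 440 called genes of 9633, 189 higher and 251 lower, and 3314 (1575 and 1739) with the replicate number as a block. CA9 (3.73 ± 0.51), NDRG1 (2.75 ± 0.24), PGK1 (1.75 ± 0.17) and P4HA2, a collagen prolyl hydroxylase (1.37 ± 0.14), were among 7 of 27 hypoxia and iron genes that rose (12 adjusted over the list alone; median 0.73, adjusted p = 1.2e-10, and adjusted p = 0.013 with an estimated correlation, 0.12 in the blocked fit). GDF15 (2.52 ± 0.36), CDKN1A (2.18 ± 0.36), MDM2 (2.16 ± 0.28) and BTG2 (1.99 ± 0.17) were among 10 of 26 p53 targets that rose (19 rose and 1 fell adjusted over the list alone; median 0.86, adjusted p = 1.8e-13, and adjusted p = 0.045 with an estimated correlation, 0.12 in the blocked fit). Histone genes had 7 of 44 risen and 16 adjusted over the list alone, among them the linker histone HIST1H1A (2.07 ± 0.19), HIST1H3D (1.83 ± 0.24) and HIST1H4I (1.65 ± 0.37); the median was 0.63 (adjusted p = 4.8e-13, but adjusted p = 0.10 with an estimated correlation). LINC01705 (2.95 ± 0.20), PURPL (2.61 ± 0.20), TRIML2 (2.37 ± 0.33), SAT1 (2.30 ± 0.31) and TXNIP (2.24 ± 0.30) rose, and HNRNPA1P3 was listed at 0 in asynchronous cells against 1.79 RPKM.

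KIF20A (-1.99 ± 0.23), CDC20 (-1.98 ± 0.27), CCNB1 (-1.51 ± 0.16) and DLGAP5 (-0.86 ± 0.17) were among 5 of 45 G2/M genes that fell in nuclear input RNA, with 1 risen (9 and 1 adjusted over the list alone; adjusted p = 0.0084, but adjusted p = 0.54 with an estimated correlation). The G2/M median was -0.31 among libraries numbered 1 and 0.0067 among those numbered 2. MCM6 (-1.40 ± 0.18) and MCM3 (-1.11 ± 0.14) were among 5 of 47 G1/S genes that fell (7 adjusted over the list alone), and that list did not pass camera (adjusted p = 0.56). Ribosomal protein genes had 30 of 63 fallen and 55 adjusted over the list alone, with RPS23 at -1.55 ± 0.26 (median -0.90, adjusted p = 5.3e-32, but adjusted p = 0.10 with an estimated correlation). The snoRNA hosts SNHG8 (-1.64 ± 0.30), GAS5 (-1.52 ± 0.32) and SNHG15 (-1.34 ± 0.28) were among 6 of 14 that fell (11 adjusted over the list alone; median -1.12, adjusted p = 6.3e-10, but adjusted p = 0.10 with an estimated correlation). Interferon genes (median 0.27) and NF-kB and cytokine genes (0.17) did not pass (adjusted p = 0.054 each) and did with the block (adjusted p = 0.04975 each, but adjusted p = 0.68 each with an estimated correlation). Counts per window were 357 at T0-2, 260 at T2-4, 105 at T4-6, 85 at T6-8 and 19 at T8-10, and 3452, 3152, 1952, 2094 and 1414 with the block. Without asynchronous replicate 1 no gene passed for the mean of windows, the lowest count, and without replicate 1 of T2-4 there were 287, the highest. The lists not named above for a table did not pass camera there: among them sterol genes and NRF2 targets in all 4 tables (adjusted p of at least 0.14), nuclear lncRNAs (at least 0.42) and pigment epithelium genes where tested (at least 0.55). The 3 measured markers of other cell types in whole-cell nascent RNA had a median of -1.22 (0 called, 2 fallen adjusted over the list alone), HBB among them at -0.39 ± 1.25.

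Genes that differed among the 5 windows were few in the tests of all window means. In nuclear input RNA 21 genes passed, 14 of them highest at T4-6 and 17 lowest at T0-2. They were mostly replication-dependent histone genes such as HIST1H1A, HIST2H3D, HIST1H2AB and HIST1H3H (adjusted p = 0.021 each), while HK2, a hexokinase, GFPT2, LINC01705 and R3HCC1 were highest at T0-2. The blocked test gave 1262. In nuclear nascent RNA LINC01705 and R3HCC1 passed (adjusted p = 0.033 and 0.037), both highest at T0-2. No gene passed limma's F-test in whole-cell nascent RNA (313 at an unadjusted p under 0.05) or whole-cell input RNA (126), where blocked tests over the window libraries alone gave 26 and 320. The nuclear input count was 0 without asynchronous replicate 1 and 11 without replicate 1 of T2-4, its lowest and highest. The nuclear nascent count was 0 without replicate 1 of T0-2 and 5 without replicate 1 of T8-10, and the whole-cell nascent count was 2 without replicate 1 of T0-2.

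T8-10 against T0-2 gave these differences a direction. In nuclear input RNA 16 of 44 histone genes were higher at T8-10 and 37 adjusted over the list alone, led by HIST1H2BE (3.26 ± 0.46, 21.4 against 2.05 RPKM; 2 libraries each; limma adjusted p = 0.031) and HIST1H2AE (2.89 ± 0.32). The list's median was 1.92 (adjusted p = 2.0e-34, and adjusted p = 0.028 with an estimated correlation, 0.18 in the blocked fit). Cyclin E1 gene CCNE1 (-1.73 ± 0.25) was the 1 fallen gene of 47 G1/S genes (9 adjusted over the list alone; adjusted p = 2.2e-19, but adjusted p = 0.056 with an estimated correlation). NDRG1 (-2.60 ± 0.31) and HK2 (-2.17 ± 0.25) fell among 27 hypoxia and iron genes, and 9 fell and 1 rose adjusted over the list alone (median -0.48, adjusted p = 9.4e-11, and adjusted p = 0.012 with an estimated correlation, 0.12 in the blocked fit). SPRY4, an inhibitor of growth factor signalling, changed by -2.82 ± 0.43. In all, 26 genes rose and 14 fell, and 1492 and 650 with the block. The count was 0 without replicate 1 of T0-2 and 26 without replicate 1 of T2-4. The median of all genes was 0.12 in nuclear input and 0.15 in nuclear nascent RNA.

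In nuclear nascent RNA 11 genes rose and 24 fell from T0-2 to T8-10, and few passed without T0-2 replicate 1. PLK1 rose by 2.01 ± 0.28 (3.21 against 0.637 RPKM), while cyclin E2 gene CCNE2 (-2.25 ± 0.24), the MAP kinase phosphatases DUSP6 (-2.85 ± 0.47) and DUSP5 (-2.42 ± 0.33), PTGS2 (-2.52 ± 0.35), NDRG1 (-2.02 ± 0.34) and HK2 (-1.70 ± 0.22) fell. No gene passed limma in whole-cell nascent RNA (767 at an unadjusted p under 0.05) or whole-cell input RNA (380). Windows of the same number deviated together there (correlations across genes of 0.54 and 0.94 between T0-2 and T8-10), and the block gave 2 risen and 3 fallen genes in the former and 5 fallen in the latter. In whole-cell input RNA 4 lists without called genes passed camera downward with both settings: hypoxia and iron genes (median -1.18, 8 of 29 adjusted over the list alone; adjusted p = 0.0033 with an estimated correlation), immediate early genes (-1.06, 4 of 24; 0.0040), G1/S genes (-0.65, 0 of 46; 0.032) and NF-kB and cytokine genes (-0.38, 1 of 20; 0.034). G2/M genes had medians of 0.93, 0.79, 0.43 and 0.58 in whole-cell nascent, whole-cell input, nuclear nascent and nuclear input RNA (adjusted p = 2.6e-17, 5.5e-09, 9.4e-05 and 1.7e-08). They had adjusted p = 0.23, 0.36, 0.31 and 0.16 with an estimated correlation. The p53 list had medians above 0 against asynchronous cells at T8-10 in each table, 0.80 to 1.16. The hypoxia and iron list had medians of 0.97 to 1.75 at T0-2 and 0.17 to 0.64 at T8-10.

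**Figure D1:**
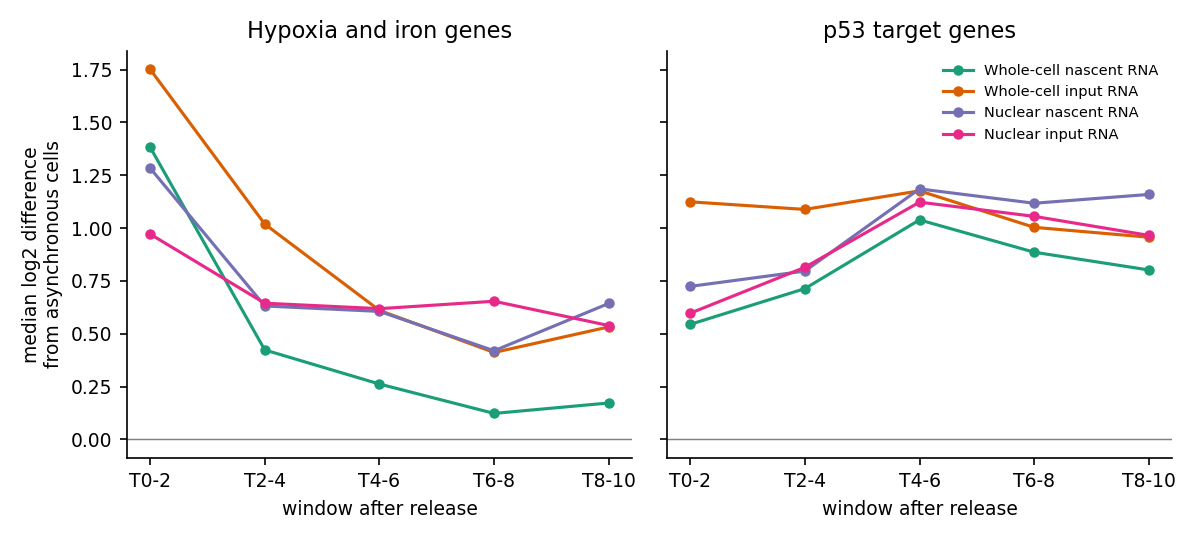
Median log2 difference from asynchronous cells (y axis) of hypoxia and iron genes (left, 27 to 29 genes) and p53 targets (right, 24 to 26 genes) in each window (x axis), 1 line per kind of RNA, each point from 2 libraries against 2. The hypoxia medians are highest at T0-2 (0.97 to 1.75) in all 4 kinds of RNA, and those of p53 targets are 0.80 to 1.16 at T8-10.

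The same tables held the 3 RNAs later knocked down. LUCAT1 (chromosome 5, 91302986 to 91314402, GRCh38.p14) was higher in the windows in nuclear input RNA, at 0.962 ± 0.716 (SD, n = 10) against 0.226 ± 0.0148 RPKM (n = 2), a difference of 1.19 ± 0.18 (limma adjusted p = 0.011). Its differences of 0.46 ± 0.32, 0.75 ± 0.18 and 0.81 ± 0.30 in whole-cell nascent, whole-cell input and nuclear nascent RNA did not pass (adjusted p = 0.55, 0.20 and 0.16). The window mean hides a decline. Nuclear input RNA had 2.73 and 1.67 RPKM at T0-2 and 0.514 and 0.533 at T8-10, against 0.236 and 0.215 in asynchronous cells. Nuclear nascent RNA had 4.31 and 1.78, then 0.432 and 0.534, against 0.333 and 0.492. LINC00704 (MANCR in the tables; chromosome 10, 4650185 to 4678070) had 3.85 ± 0.904 against 1.84 ± 0.186 RPKM in whole-cell nascent RNA, a difference of 0.94 ± 0.28 that did not pass (adjusted p = 0.19), and 0.27 ± 0.48, 0.66 ± 0.26 and 0.57 ± 0.35 in the other tables (adjusted p = 1.0, 0.18 and 0.44; 0.0074 for nuclear input RNA with the block). MIAT (chromosome 22, 26646429 to 26676478) had 1.01 ± 0.28 in nuclear nascent RNA and 0.83 ± 0.29 in nuclear input RNA (adjusted p = 0.077 and 0.16) and lay below the filter in whole cells. Adjusted over the 3 alone, 3 rose in nuclear nascent, 2 in nuclear input and 1 of 2 in each whole-cell table. They may have been picked for such rises, biasing these counts. No measured neighbour of a target passed.

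Each targeted RNA was lower in every synchronised knockdown library than in every control library of its table. LINC00704 had 0.948 ± 0.327 RPKM after knockdown against 3.13 ± 0.727 in controls (SD, n = 8 each), 30.3% of control (ranges 0.550 to 1.61 and 1.89 to 4.04; a log2 difference of -1.51 ± 0.16, limma adjusted p = 0.0026). LUCAT1 had 0.240 ± 0.0864 against 0.718 ± 0.165 RPKM, 33.4% (0.133 to 0.379 and 0.440 to 0.994; -0.98 ± 0.14, adjusted p = 0.0013). MIAT had 0.134 ± 0.0557 against 0.277 ± 0.0331 RPKM, 48.3% (0.0718 to 0.221 and 0.243 to 0.323), below the filter; without a filter its difference was -0.47 ± 0.08 (adjusted p = 0.0051). Exact permutation within points gave p = 0.00154 for each, two-sided, the smallest that 1296 arrangements allow. In asynchronous cells LINC00704 was at 34.3% of control (-1.26 ± 0.18, adjusted p = 0.096), LUCAT1 at 39.0% and MIAT at 26.2% (0.0948 ± 0.0504, n = 3, against 0.362 ± 0.0241 RPKM, n = 2). LUCAT1 had 0.311, 0.128 and 0.124 RPKM in its knockdown replicates 1, 2 and 3, against 0.469 and 0.495 in controls, and without replicate 1 it was at 26.2% of control. For the 3 RNAs the exact permutation p was 0.10, 0.20 and 0.10, and 10 arrangements allow none under 0.10. The authors' deposited table gave log2 fold changes of -1.41, -1.02 and -1.24 for the same 3 (FDR 2.7e-04, 9.0e-08 and 1.9e-35). Among the other targets, LUCAT1 rose in asynchronous MIAT knockdown (0.49 ± 0.09, adjusted p = 0.0070). It had differences of 0.56 ± 0.13 and 0.66 ± 0.16 in synchronised and asynchronous LINC00704 knockdown that did not pass (adjusted p = 0.26 and 0.20). MIAT was at 0.166 ± 0.0840 (n = 3) against 0.375 ± 0.0253 RPKM (n = 2) in asynchronous LUCAT1 knockdown, with every knockdown library (0.0936 to 0.258) below both controls, but below the filter (exact permutation p = 0.20). The authors' deposited table gave it -0.83 (FDR 2.5e-06). For asynchronous MIAT knockdown the authors' deposited table gave LINC00704 0.42 (FDR 4.2e-06) and LUCAT1 0.60 (FDR 4.0e-06), while limma gave LINC00704 0.37 ± 0.20 (adjusted p = 0.18).

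**Figure D2:**
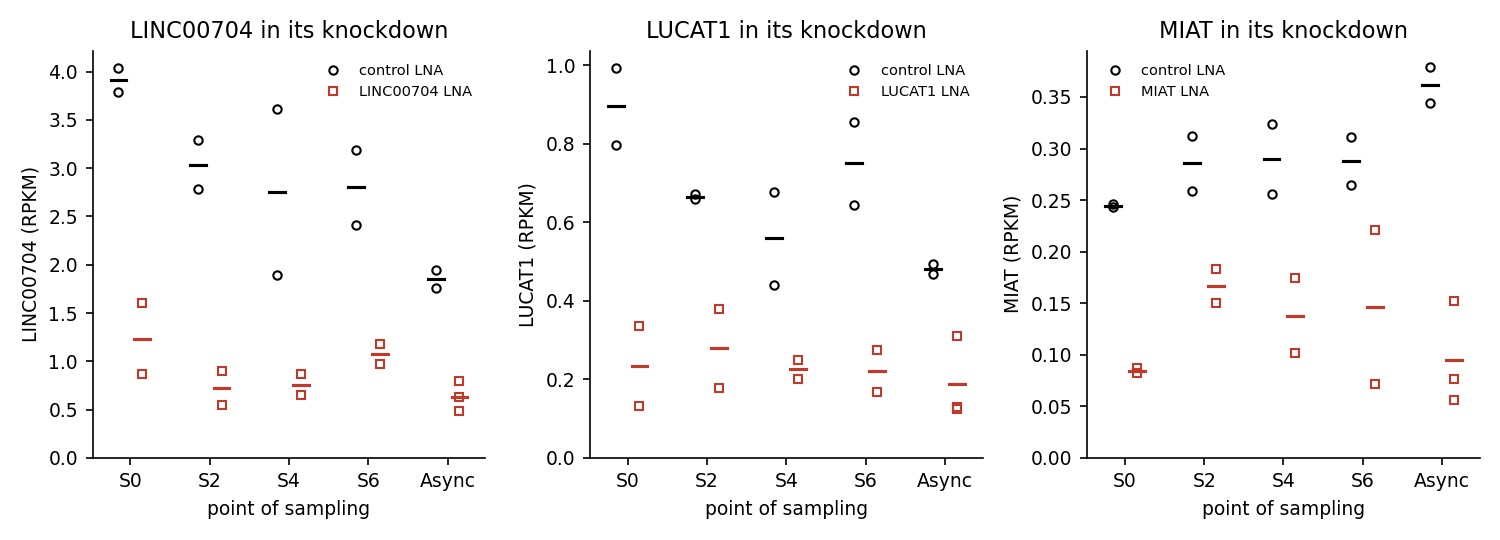
RPKM (y axis) of each targeted RNA in control and knockdown libraries at each point (x axis), with 1 symbol per library and a bar at the mean of 2 or 3 libraries. In synchronised cells every knockdown library lies below every control library, with means of 0.948 against 3.13 (LINC00704), 0.240 against 0.718 (LUCAT1) and 0.134 against 0.277 RPKM (MIAT).

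The control libraries gave the time course behind the knockdowns. The same 8 stand in all 3 synchronised tables, and each fit shares its filter and spread with the knockdown libraries of its table. The LUCAT1 table, fixed beforehand for the test among points, gave the values here. From S0 to S6, HIST1H2BG rose by 6.33 ± 0.56 (360 against 4.04 RPKM, n = 2 each; limma adjusted p = 1.6e-04), HIST1H2BB by 6.11 ± 0.88 and HIST1H2BM by 5.84 ± 0.44. Of 45 histone genes 31 rose and 41 adjusted over the list alone (median 2.79, adjusted p = 5.6e-81, and adjusted p = 0.014 with an estimated correlation). Of 30 hypoxia and iron genes 8 fell and 17 adjusted over the list alone, among them ANKRD37 (-2.39 ± 0.37), INSIG2 (-1.93 ± 0.28), HK2 (-1.75 ± 0.35) and AK4 (-1.75 ± 0.29); the list had a median of -1.17 (adjusted p = 6.8e-26, but adjusted p = 0.088 with an estimated correlation). Of the histone genes 3 and 28 rose in the LINC00704 and MIAT tables (43 adjusted over the list alone in each), and 0 and 9 hypoxia and iron genes fell (19 and 17). With an estimated correlation the histone list had adjusted p = 0.096 and 0.028 there, and the hypoxia and iron list adjusted p = 0.15 and 0.028. In all 52 genes rose and 34 fell in the LUCAT1 table (18 in total without control S0 replicate 1) and 50 and 45 in the MIAT table. The LINC00704 table gave 7 risen and 0 fallen genes with limma (857 at an unadjusted p under 0.05), HIST1H2BG (adjusted p = 0.048) among the risen. The other histone and hypoxia genes just named had adjusted p = 0.059 to 0.15 there, and INSIG2 had 0.15 in the MIAT table. Among the 4 points 40 genes differed in the LUCAT1 table, 47 in the MIAT table and 0 in the LINC00704 table with limma (478 at an unadjusted p under 0.05). Of the 40, 25 were highest at S6, TXNIP among them, and 13 at S0, with the growth factor antagonist SPRY1. The count was 12 without control S0 replicate 1 and 33 without S4 replicate 1. Histone genes took 0.141% to 0.216% of reads at S0 and 0.894% to 1.15% at S6 in controls. On non-histone genes that changed with time, scaled so that control S0 is 0 and control S6 is 1, the LINC00704 library labelled S2 column 1 scored 1.03 and the one labelled S4 column 1 scored 0.15, outside the 0.53 to 0.68 and 0.76 to 0.90 of the other libraries of their points. The MIAT library labelled S6 column 1 scored 0.59, the lowest at S6.

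**Figure D3:**
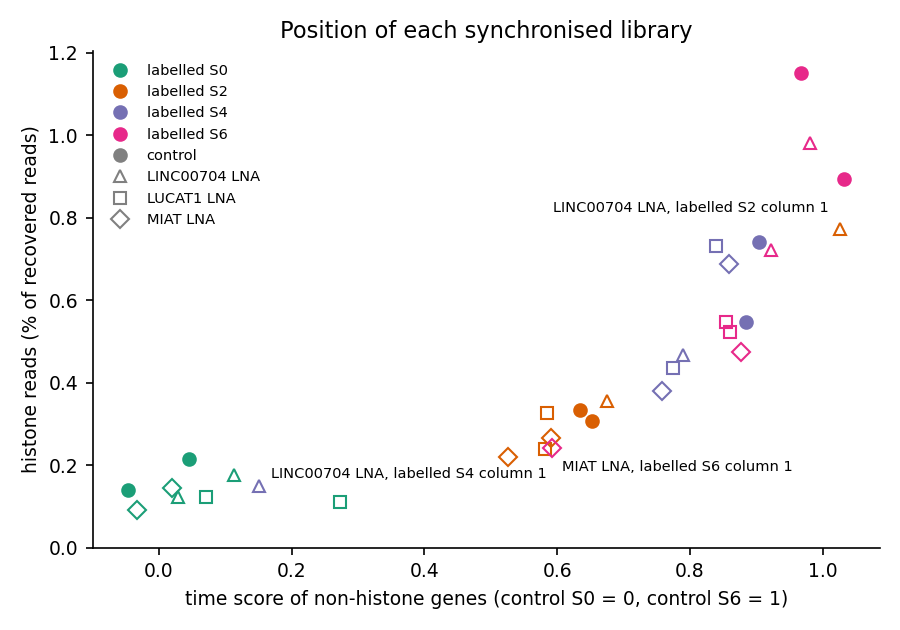
Share of reads in histone genes (y axis, percent of recovered reads) against the time score of non-histone genes (x axis, control S0 = 0 and control S6 = 1), 1 symbol per synchronised library, colour for the labelled point and shape for the LNA. The LINC00704 libraries labelled S2 column 1 (score 1.03) and S4 column 1 (0.15) lie apart from the others of their points, as does the MIAT library labelled S6 column 1 (0.59).

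Knockdown of LINC00704 in synchronised cells changed 2 of 9442 genes, LINC00704 itself and the lncRNA AL158212.3 (-0.88 ± 0.12, adjusted p = 0.020, named after its value was seen). At an unadjusted p under 0.05 there were 1559, and single points gave 0 called genes with limma (79, 175, 498 and 109 unadjusted at S0, S2, S4 and S6). The neighbours KLF6 (0.03 ± 0.16) and PFKP (-0.38 ± 0.18), 864976 and 1513380 bp from LINC00704, did not pass. Without the libraries labelled S2 column 1 and S4 column 1, which stood apart above, 1 gene passed, and without S0 column 3 there were 1037, while without control S0 replicate 2 there was 1. Apart from LINC00704 itself among the targets, no list held a called gene. Extracellular matrix genes (median -0.23, 5 of 23 fallen adjusted over the list alone; adjusted p = 3.1e-06), G1/S genes (-0.12, 0 of 46; 1.8e-05), ATF4 genes (-0.12, 1 of 29; 0.0016) and, upward, interferon genes (0.33, 5 of 15; 2.2e-04) passed camera, each with adjusted p = 0.29 with an estimated correlation. Histones (-0.23, 0 of 46; adjusted p = 2.4e-05) and G2/M genes (-0.03, 0 of 44; 0.018) had adjusted p = 0.66 with an estimated correlation. Without the libraries labelled S2 column 1 and S4 column 1, medians were -0.14 for histones, -0.10 for matrix genes and -0.08 for G2/M genes. That fit leaves 1 knockdown library at each of these points, and camera was not run on it with an estimated correlation. Ribosomal protein genes (-0.05, 0 of 62; adjusted p = 0.0072) had adjusted p = 0.77 with an estimated correlation and a median of 0.09 (adjusted p = 0.45) under quantile normalization.

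Knockdown of LUCAT1 in synchronised cells changed 2680 of 9870 genes, 1879 upward and 801 downward. Of the extracellular matrix genes, LOX, which crosslinks collagen (-1.59 ± 0.27, 4.72 against 13.8 RPKM; 8 libraries each; adjusted p = 0.0029), the collagen COL4A2 (-1.23 ± 0.18) and TGFBI (-0.95 ± 0.18) were among 13 of 23 that fell (13 adjusted over the list alone; median -0.56, adjusted p = 2.7e-10, but adjusted p = 0.32 with an estimated correlation). Of 15 snoRNA hosts 11 rose with both adjustments, such as SNHG15 (1.44 ± 0.14), GAS5 (1.30 ± 0.27), SNHG1 (1.04 ± 0.29) and ZFAS1 (0.86 ± 0.23; list median 0.80, adjusted p = 1.6e-04, but adjusted p = 0.32 with an estimated correlation). ARRDC3, 54229 bp from LUCAT1 and a regulator of receptor trafficking, rose by 1.39 ± 0.27 (10.9 against 4.05 RPKM; adjusted p = 0.0056). It was the 1 of 5 neighbours to pass (2 adjusted over the list alone). PFKP (-0.64 ± 0.18), a neighbour of LINC00704, and TPST2 (-0.45 ± 0.11), a neighbour of MIAT, fell. The risen genes with the largest changes were weak, BICD1P1 (2.99 ± 0.16, 2.08 against 0.0344 RPKM), ACTBP14 (2.86 ± 0.19), RN7SL475P (2.52 ± 0.40), PRXL2AP2 (2.44 ± 0.36) and the platelet glycoprotein gene GP5 (2.35 ± 0.28).

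The growth factor receptor gene PDGFRB (-1.32 ± 0.15), GDF6 (-1.42 ± 0.27), PPDPF (-1.43 ± 0.33) and C1QL1 (-1.31 ± 0.14) also fell after LUCAT1 knockdown. Of 45 histone genes 7 fell with both adjustments, such as HIST1H4J (-1.75 ± 0.29), HIST1H4A (-1.13 ± 0.18) and HIST1H4E (-1.07 ± 0.24; list median -0.36, adjusted p = 3.3e-07, but adjusted p = 0.72 with an estimated correlation). Of 7 other RNAs without poly(A) tails 3 fell (median -0.25), with RNU4-1 at -3.98 ± 0.74 and RNU4-2 at -3.85 ± 0.69, named after their values were seen. CA9 (-1.05 ± 0.30) and VEGFA (-0.89 ± 0.21) were among 7 of 30 hypoxia and iron genes that fell, with 1 risen (adjusted p = 6.1e-04, but adjusted p = 0.74 with an estimated correlation). GDF15 (-1.08 ± 0.26), CDKN1A (-1.05 ± 0.19, 109 against 221 RPKM) and BAX (-0.77 ± 0.21) were among 6 of 25 p53 targets that fell, with 1 risen (adjusted p = 0.033, but adjusted p = 0.72 with an estimated correlation). Of G1/S genes 10 of 48 rose and 2 fell, among them UNG (0.87 ± 0.18), the histone mRNA-binding gene SLBP (0.77 ± 0.17) and CCNE2 (0.72 ± 0.16). Of G2/M genes 6 of 46 fell and 2 rose, PRC1 by -0.69 ± 0.15 (2 and 1 adjusted over the list alone; adjusted p = 0.046, but adjusted p = 0.85 with an estimated correlation). The chaperones PDIA4 (-0.97 ± 0.17) and HSPA5 (-0.92 ± 0.18) were among 8 of 29 ATF4 and unfolded protein response genes that fell, while 5 rose. Of 23 sterol genes 6 rose and 3 fell, SC5D by 0.83 ± 0.15, and of 23 NF-kB and cytokine genes 4 rose and 1 fell, CXCL8 by 1.02 ± 0.31. Except for G2/M, these counts of hypoxia, p53, G1/S, ATF4, sterol and NF-kB genes were equal adjusted over the list alone. The G1/S, ATF4, sterol and NF-kB lists did not pass camera. Neither did the immediate early (3 risen, 4 fallen of 24), interferon (4 and 1 of 14), NRF2 (3 and 0 of 15), nuclear lncRNA (1 and 1 of 8), pigment epithelium (1 and 1 of 5) and ribosomal protein lists (5 and 0 of 63, and 2 adjusted over the list alone).

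The median of all genes was 0.11 after LUCAT1 knockdown, and median scaling gave 1072 risen and 1182 fallen genes, quantile normalization 922 and 1154, and removal of a gene-length trend 1271 and 1212. The excess of risen genes is therefore not kept with the first pair of settings and smaller with the last. Single points gave 5, 2, 10 and 3 called genes at S0, S2, S4 and S6, all higher, and no gene's effect differed between points (limma's F-test, 39 at an unadjusted p under 0.05). The count of calls was 1458 without S2 column 2 and 3779 without S0 column 3, the lowest and highest over the 16 libraries.

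Knockdown of MIAT in synchronised cells changed 727 of 9528 genes, 461 upward and 266 downward. The histone genes HIST1H4J (-2.37 ± 0.31), HIST1H2BL (-1.12 ± 0.27), HIST1H2BE (-1.11 ± 0.31) and HIST1H4E (-1.09 ± 0.20, 454 against 1053 RPKM) were among 13 of 45 that fell (28 adjusted over the list alone; median -0.78, adjusted p = 2.7e-13, but adjusted p = 0.78 with an estimated correlation). The MIAT library labelled S6 column 1 had the lowest histone share at S6, 0.242% of reads, and without it the median was -0.64 and 11 histones fell. Of 7 other RNAs without poly(A) tails 3 fell too (median -0.91), with RNU4-1 at -4.35 ± 0.63 and RNU4-2 at -3.93 ± 0.51, named after their values were seen. The mitotic genes UBE2C (-0.70 ± 0.16), AURKB (-0.67 ± 0.16) and FOXM1 (-0.55 ± 0.13) fell among 44 (20 adjusted over the list alone; median -0.43, adjusted p = 3.4e-08), as did POLA2 (-0.52 ± 0.14) and CCNE1 (-0.42 ± 0.12) among 44 G1/S genes (0 adjusted over the list alone; -0.31, 3.0e-06). Both lists had adjusted p = 0.78 with an estimated correlation. GAS5 (1.32 ± 0.25), SNHG15 (1.15 ± 0.24) and ZFAS1 (0.90 ± 0.19) rose among 14 snoRNA hosts (9 rose and 1 fell adjusted over the list alone; median 0.51, adjusted p = 2.2e-04, but adjusted p = 0.78 with an estimated correlation). TRIB3 (1.06 ± 0.26; adjusted p = 0.028, and 0.086 without S0 column 2) and the cystine transporter gene SLC7A11 (0.81 ± 0.22) were among 4 of 29 ATF4 genes that rose, and 3 fell (6 and 6 adjusted over the list alone), in a list that did not pass camera.

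The lncRNA LINC00565 was at 21.2 against 1.90 RPKM after MIAT knockdown (3.10 ± 0.34; 8 libraries each; adjusted p = 4.1e-04). BICD1P1 (3.55 ± 0.34), ACTBP14 (3.53 ± 0.25), GP5 (3.42 ± 0.30), FAM83E (2.71 ± 0.33), AMN (2.65 ± 0.33) and APOL1 (2.49 ± 0.28) also rose. HMGN2, a nucleosome-binding protein gene (-1.21 ± 0.20), C1QL1 (-1.25 ± 0.16) and TUBB2A (-1.02 ± 0.18) fell. LncRNAs rose in 17.8% of 713, against 3.02% of 8435 coding genes (Fisher's exact test, adjusted p = 1.3e-48). Coding genes matched on RPKM and length gave 15.3%. No measured neighbour of MIAT passed (HPS4 0.31 ± 0.09, adjusted p = 0.064; 1 of 5 adjusted over the list alone). S6 alone gave 115 risen and 14 fallen genes, S2 gave 1, and S0 and S4 gave 0 with limma (537 and 550 at an unadjusted p under 0.05). No gene passed the F-test for an effect that differed between points (110 of 9528 unadjusted). That share too is below 0.05, so equal effects at the 4 points are not shown. The S6 count was 0 without control S6 replicate 1, 337 without S4 column 2 and 13 without S6 column 1. The count over the 4 points was 393 without S0 column 2, 986 without S0 column 3 and 838 (471 and 367) without S6 column 1.

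In asynchronous cells LINC00704 knockdown raised 5 of 8975 genes (1115 at an unadjusted p under 0.05): APOL1, a lipid-binding protein gene (1.82 ± 0.13, 1.34 against 0.202 RPKM; 3 and 2 libraries; limma adjusted p = 0.018), and, named after their values were seen, AC005696.3 (2.89 ± 0.30), ASS1P5 (1.59 ± 0.16), DCAF4L1 (1.48 ± 0.13) and SLC22A14 (1.39 ± 0.12). No gene passed without control replicate 1, and 39 did without knockdown replicate 3, 34 higher and 5 lower. Histones (median -0.43, 0 of 48 called, 16 fallen adjusted over the list alone; camera adjusted p = 3.1e-11), extracellular matrix genes (-0.65, 12 of 21; 2.3e-09) and G1/S genes (-0.27, 0 of 45; 4.9e-06) passed downward. The p53 targets (0.28, 0 of 22; 1.2e-08), immediate early genes (0.13, 3 of 21; 4.6e-05) and interferon genes (0.21, 0 of 14; 0.0019) passed upward. Each had adjusted p = 0.24 with an estimated correlation. NRF2 targets (-0.29, 1 of 15; adjusted p = 0.033) and G2/M genes (-0.14, 0 of 44; 0.048) had adjusted p = 0.35 and 0.72 with an estimated correlation. CDKN1A had 0.66 ± 0.18, not passing alone.

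LUCAT1 knockdown in asynchronous cells raised 20 of 9550 genes (2100 at an unadjusted p under 0.05), among them PRXL2AP2 (3.71 ± 0.36), RNF151 (2.32 ± 0.20), the bile acid receptor gene GPBAR1 (2.14 ± 0.17) and the apolipoprotein gene APOE (1.94 ± 0.18, 1.71 against 0.262 RPKM; adjusted p = 0.040). No gene passed without control replicate 1, and 4596 did without knockdown replicate 1, 1766 higher and 2830 lower. That library, with the highest LUCAT1 level of the 3, had -15.6 on the first principal component, against -31.9 and -29.3 in controls and 42.2 and 34.7 in the other knockdown libraries. Without it 44 of 48 histones fell and 3 rose (median -1.43), 16 of 22 p53 targets rose and 1 fell (1.04), equal adjusted over the list alone, and 19 of 21 matrix genes fell (20 adjusted over the list alone; -1.58). These lists then had adjusted p = 0.25 with an estimated correlation. NRF2 targets, at adjusted p = 0.073 with all libraries, passed camera without it (median -0.72, 10 of 16 fallen and 1 risen with both adjustments; adjusted p = 0.014, but adjusted p = 0.31 with an estimated correlation). With all libraries, histones had a median of -1.28 with 0 of 48 called (44 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.2e-20, but adjusted p = 0.42 with an estimated correlation), and HIST1H3B had 405 against 944 RPKM (-1.23 ± 0.22, adjusted p = 0.077). The p53 targets had a median of 0.84 (0 called, 7 of 22 risen adjusted over the list alone; adjusted p = 1.7e-09, but adjusted p = 0.42 with an estimated correlation). Extracellular matrix genes had -1.24 (17 of 21 fallen adjusted over the list alone; adjusted p = 9.8e-08), hypoxia and iron genes -0.39 (1 of 28; 6.7e-04) and sterol genes -0.46 (0 of 24; 0.0061), NF-kB and cytokine genes 0.42 (1 risen and 1 fallen of 19; 6.7e-04), and immediate early genes 0.13 (4 risen and 3 fallen of 23; 0.0071), each with adjusted p = 0.54 with an estimated correlation. G2/M genes (-0.46, 8 of 45; adjusted p = 1.2e-05) had adjusted p = 0.57 with an estimated correlation. Ribosomal protein genes (-0.39, 0 of 63; adjusted p = 6.5e-05, and adjusted p = 0.64 with an estimated correlation) had a median of 0.15 under quantile normalization. ARRDC3 had 0.41 ± 0.24, not passing. The median of all genes was -0.10.

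MIAT knockdown in asynchronous cells changed 4016 of 9200 genes, 1155 upward and 2861 downward. Of the G1/S genes, TK1, thymidine kinase (-1.28 ± 0.14, 6.21 against 15.3 RPKM; 3 and 2 libraries; adjusted p = 0.0012), the helicase subunit MCM2 (-1.12 ± 0.16), E2F1 (-1.05 ± 0.11) and UHRF1 (-1.05 ± 0.10) were among 25 of 46 that fell, with 1 risen, in both adjustments (median -0.50, adjusted p = 3.8e-04, but adjusted p = 0.83 with an estimated correlation). Of 47 histone genes 34 fell and 1 rose (39 and 1 adjusted over the list alone), HIST1H4A by -1.42 ± 0.15 and HIST2H2AB by -1.26 ± 0.15 (median -0.77, adjusted p = 5.6e-07, but adjusted p = 0.72 with an estimated correlation). The collagens COL1A1 (-1.75 ± 0.21), COL4A1 (-1.19 ± 0.13) and COL4A2 (-1.08 ± 0.12) were among 14 of 21 matrix genes that fell (16 adjusted over the list alone; adjusted p = 0.0011), and MVD (-0.97 ± 0.12) among 14 of 23 sterol genes (2 rose in both adjustments; adjusted p = 0.027). Interferon genes had 8 of 15 risen and 2 fallen (8 and 3 adjusted over the list alone), ISG20 by 1.19 ± 0.14 and SAMD9 by 0.87 ± 0.09 (adjusted p = 0.0030). Of 13 snoRNA hosts 6 rose in both adjustments, GAS5 by 1.00 ± 0.13 and SNHG1 by 0.78 ± 0.17 (adjusted p = 0.0010). These 4 lists had adjusted p = 0.61 with an estimated correlation.

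ACTBP14 (4.71 ± 0.20), RF00001 (4.56 ± 0.39), GP5 (3.92 ± 0.11), BICD1P1 (3.20 ± 0.09) and LINC00565 (2.98 ± 0.25) had the largest rises after asynchronous MIAT knockdown. BIRC5, survivin (-1.01 ± 0.19), TACC3 (-0.97 ± 0.10) and PLK1 (-0.92 ± 0.12) were among 11 of 44 G2/M genes that fell, and SDF2L1 (-1.22 ± 0.10) and CRELD2 (-1.04 ± 0.09) among 8 of 28 ATF4 and unfolded protein response genes, while 5 rose. The cytokine gene IL1B (1.96 ± 0.13, 5.69 against 1.26 RPKM) was among 4 of 15 NF-kB and cytokine genes that rose, with 3 fallen. RRM2B (0.70 ± 0.12) and MDM2 (0.66 ± 0.18) were among 4 of 22 p53 targets that rose, with 1 fallen, and DUSP6 (1.00 ± 0.09) among 4 of 20 immediate early genes, with 2 fallen. MIR210HG (-0.97 ± 0.13) was among 6 of 28 hypoxia and iron genes that fell. Of 15 NRF2 targets 5 fell and 2 rose. Ribosomal protein genes had 2 of 62 risen and 7 fallen. None of these lists passed camera. Adjusted over the list alone, their risen and fallen counts were 0 and 11 (G2/M), 5 and 8 (ATF4), 5 and 4 (NF-kB), 3 and 1 (p53), 3 and 2 (immediate early), 0 and 4 (hypoxia and iron), 2 and 6 (NRF2) and 1 and 0 (ribosomal). The neighbours TFIP11 (-0.34 ± 0.09) and TPST2 (-0.53 ± 0.09) of MIAT, 133956 and 56297 bp from it, fell, as did PFKP (-0.65 ± 0.10). Of the neighbours of LUCAT1, LYSMD3 (0.86 ± 0.16), 773402 bp away, and ARRDC3 (0.39 ± 0.13), 54229 bp away, rose. LncRNAs rose in 39.0% of 462, against 10.2% of 8047 coding genes (Fisher's exact test, adjusted p = 1.1e-53). The median of all genes was -0.12, and median scaling gave 1863 risen and 1979 fallen genes, quantile normalization 1358 and 1701, so the excess of fallen genes is smaller there. It turned to 1914 risen and 1710 fallen with a gene-length trend removed. The count was 1616 without control replicate 1 and 4652 without knockdown replicate 1.

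The knockdowns share control libraries, and so part of any overlap may come from them. In synchronised cells LUCAT1 and MIAT knockdown shared 269 risen genes (60.2 for independent lists) and 148 fallen ones (22.97), with 3 in opposite directions. Their log2 changes correlated across genes, which are not independent, at r = 0.70, against 0.50 for simulated unchanged groups, with a covariance of 0.118 against 0.0156. With controls split between the comparisons r was 0.34 or 0.44. The shared genes were then 5 risen (0.600 for independent lists) and 0 fallen, or 2 risen (0.0337) and 0 fallen. Fewer genes were called in those fits, MIAT knockdown having 18 or 4 risen and 1 fallen. LINC00704 gave r = 0.73 with LUCAT1 (0.50 simulated; covariance 0.0775 against 0.0157; 0.24 or 0.30 split) and 0.59 with MIAT (0.50; 0.0521 against 0.0154; 0.03 or 0.20). In asynchronous cells r was 0.61, 0.77 and 0.59 for LINC00704 with LUCAT1, LINC00704 with MIAT and LUCAT1 with MIAT, against 0.60, 0.61 and 0.62 simulated, with covariances of 0.0888, 0.102 and 0.141 against 0.0333, 0.0169 and 0.02501. Among genes measured in both comparisons there, all 5 raised by LINC00704 knockdown (0.479 for independent lists) and all 18 raised by LUCAT1 knockdown (1.83) also rose with MIAT knockdown. LINC00704 and LUCAT1 knockdown, with 3 and 4 risen genes measured in both, shared 0. Splitting 2 controls leaves 1 library each, so it was not done there. Between synchronised and asynchronous cells, with other controls, each knockdown gave r = 0.70 across genes. MIAT knockdown raised 293 genes in both (42.7 for independent lists; Fisher's exact test p = 2.5e-218) and lowered 176 (75.3; p = 1.1e-42), with 9 in opposite directions, and 18 genes rose in both for LUCAT1 (3.49; p = 1.4e-13).

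The authors' deposited table listed 1093, 7153 and 8546 genes at an FDR under 0.05 for asynchronous LINC00704, LUCAT1 and MIAT knockdown, 821, 4503 and 4036 of them higher, of 14746, 16052 and 15046 genes. Among the 8975, 9550 and 9200 genes tested here the authors' deposited table had 310, 3522 and 5207 of them, against 5, 20 and 4016 called here. Of the genes called here, 5 of 5, 20 of 20 and 3960 of 4016 were among them. Log2 fold changes of the authors' deposited table and those computed here correlated across genes, which are not independent, at r = 0.992, 0.987 and 0.993.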

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

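Tests chosen after the result was seen were that of another time label on each LINC00704 column, the comparison of these columns with the range of the other point, the time scores of LUCAT1 and MIAT libraries beside their controls, and the reading of RNAs without poly(A) tails apart in synchronised and asynchronous cells. Effects differed between conditions as follows. The difference from asynchronous cells varied among the 5 windows for 2 genes in nuclear nascent RNA and 21 in nuclear input RNA (limma F-test, Benjamini-Hochberg). After MIAT knockdown the pseudogene LDHAP4 was higher in synchronised cells (1.0045 on the log2 scale) and lower in asynchronous cells (-0.86), and PDCD11, which acts in ribosomal RNA processing, had 0.53 and -0.39. Every knockdown library of each setting lay on the stated side for these genes, and the difference between the settings was not tested.

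After MIAT knockdown 18.5% of 665 lncRNAs of known length rose in synchronised and 39.0% of 462 in asynchronous cells (coding genes 2.93% and 10.2%). Coding genes matched on mean RPKM and length rose in a median of 15.3% (95% of 1000 draws 13.1% to 17.6%, highest 18.9%) and 28.1% (24.5% to 31.8%, highest 34.2%). The lncRNA share passed every draw in asynchronous but not in synchronised cells, so weak expression, short length or background reads cannot be told apart from an effect on lncRNAs as a class. Those raised in synchronised MIAT knockdown had medians of 0.43 ± 0.13 (bootstrap error; 48 of 64 higher; other lncRNAs 0.30) in asynchronous LUCAT1 and 0.36 ± 0.08 (52 of 63; others -0.02) in asynchronous LINC00704 knockdown, against 1.17 ± 0.11 (100 of 103) for MIAT. A response to knockdown LNAs in general therefore cannot be told apart from one to loss of MIAT, since these medians lie between the levels that each would need. In synchronised cells, where controls are shared, 87 of 91 of these lncRNAs were higher after LUCAT1 knockdown (median 0.74, 60 called). After LINC00704 knockdown 48 of 52 were (median 0.31, 0 called).

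Histone transcripts had negative medians in all 6 knockdown comparisons (mean -0.64). That of synchronised LINC00704 knockdown was -0.23, and -0.14 without its 2 libraries out of order. Within a setting controls are shared, so histone-rich ones could lower all its medians. In asynchronous cells 9 other RNAs without poly(A) tails did not fall as histones did, which argues against a lower yield of these 9. Their mean median was -0.0332. Their lowest values of -0.21, -0.37 and -0.44 (LINC00704, LUCAT1, MIAT) lay above the histone medians of -0.43, -1.28 and -0.77. Whether these RNAs track histone transcripts was not tested, so a lower yield of RNAs without tails is not excluded there. In synchronised cells it cannot be told apart, since 7 such RNAs had -0.42 and RNU4-1 fell with LUCAT1 (-3.98 ± 0.74) and MIAT knockdown (-4.35 ± 0.63); the mean over all 6 comparisons (-0.23, above the histones in 5) joins settings that moved apart and decides nothing. An earlier position in S phase also cannot be told apart in synchronised cells: other genes that change from S0 to S6 in controls lay toward S0 by medians of -0.0771 ± 0.0433 (LINC00704), -0.0254 ± 0.0649 (LUCAT1) and -0.121 ± 0.0262 (MIAT), beyond 2 bootstrap errors for MIAT alone, while on the time score, whose scale the controls set, every LUCAT1 and MIAT library at S2, S4 and S6 lay below both controls of its point and both LUCAT1 libraries at S0 (0.273 and 0.0714) above them. A response to loss of each RNA stays open, untested apart from these.

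The LINC00704 knockdown libraries labelled S2 column 1 and S4 column 1 were out of order in histone share and in the time score of other genes. They scored 1.03 and 0.15, against 0.53 to 0.68 and 0.76 to 0.90 in the other libraries of S2 and S4. Both lie on the side that an exchange of the 2 labels with each other needs, as the test set beforehand asked, but the exchange is excluded, since 1.03 lies above every other S4 library and 0.15 below every other S2 library. Another wrong time label on each may explain them, since 1.03 lies inside the range of S6 (0.59 to 1.0323) and 0.15 inside that of S0 (-0.05 to 0.27). No biological explanation was tested.

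Gene counts of synchronised knockdowns were set against 100 of 648 splits of the libraries within points, the real one included. For LINC00704 5 splits gave at least its 2 genes, so chance is not excluded. The highest other, with 528, points to a structure of the samples. For LUCAT1 only the real split (1) gave 2680, and the highest other gave 5. A chance split of these libraries is unlikely, but replicates may be technical. For MIAT 4 splits gave at least 727, a share just under the 0.05 set beforehand. With 100 drawn, the share over all splits cannot be placed below 0.05, so chance is not excluded. The highest other gave 2717, which points to a structure that the labels do not name.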

How the results depend on the processing

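Chosen after seeing the data were limma-voom on recovered reads, removal of a gene-length trend, the fits of the 10 window libraries alone, the fits without doubted libraries, and the control lists in the LINC00704 and MIAT tables. Of the named genes that passed, 6301 gene and setting pairs kept their direction and side of the threshold and 1734 no longer passed. Of those that had not passed, 2551 kept their side and 43 passed; none turned. For list calls 1118 kept, 146 were lost (104 of them with an estimated correlation in camera, where 12 kept) and 2 turned: ribosomal protein genes under quantile normalization had 0.0935 (adjusted p = 0.45) in synchronised LINC00704 and 0.15 (adjusted p = 5.6e-05) in asynchronous LUCAT1 knockdown. In the 10 main comparisons alone, 73 list calls became 5 with the estimated correlation. For every change given here the cause was not tested, unless fewer libraries or genes are named as the change. Depth differs between tables and libraries, and what it limits for weak genes was not tested apart.

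Windows against asynchronous cells gave 41 genes in whole-cell nascent RNA, 3 in whole-cell input, 440 in nuclear nascent and 440 in nuclear input RNA. Whole-cell nascent RNA, with 25 higher and 16 lower, gave 67 with a pseudocount of 1 (20 higher, 47 lower), 20 with 0.1 (18 and 2), 72 with no filter (21 and 51), 21 with RPKM of at least 1 (18 and 3), 94 with quantile normalization (44 and 50), 64 with no mean trend (29 and 35) and 2 with limma-voom (2 and 0). Whole-cell input RNA gave 0 with a pseudocount of 1 (852 at an unadjusted p under 0.05), 6 with quantile normalization, 10 with no mean trend, 1 with limma-voom and 6 with the length trend removed. Nuclear nascent RNA gave 244 with no filter, 229 with quantile normalization and 754 with limma-voom, and nuclear input RNA 1289 with no filter. Without 1 library each, the ranges were 3 to 27, 0 to 2, 4 to 593 and 0 to 287 in that order.

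Differences among the 5 windows gave 0, 0, 2 and 21 genes in the same order, with limma (313 and 126 at an unadjusted p under 0.05 for the whole-cell tables). Nuclear nascent RNA gave 5 with a pseudocount of 1, 4 with no filter, 4 with median scaling, 12 with quantile normalization, 1 with no mean trend, 28 with limma-voom, 5 with the length trend removed and 1 from the window libraries alone. Nuclear input RNA gave 12 with a pseudocount of 0.1, 10 with no filter, and 0 with quantile normalization, with the length trend removed and from the window libraries alone (651, 597 and 568 unadjusted). Without 1 library each, the ranges were 0 to 2, 0 to 0, 0 to 5 and 0 to 11.

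With the replicate block, windows against asynchronous cells gave 278 genes in whole-cell nascent, 191 in whole-cell input and 3314 in nuclear input RNA, and differences among windows 1, 0 and 1262. With the block over the 10 window libraries alone the latter were 26, 320 and 1509, and 0 (852 unadjusted) in nuclear nascent RNA, where the block gave 544 and 2. In asynchronous knockdowns, where 1 pair of numbers correlated at 0.33, 0.32 and 0.14, the block gave 153 genes for LINC00704 (68 higher, 85 lower), 482 for LUCAT1 (243 and 239) and 3368 for MIAT (979 and 2389), against 5 and 0, 20 and 0, and 1155 and 2861 without it. Control cells gave 55 genes among points with the block, with correlations of 0.07 to 0.75 between pairs. Of named genes 14 no longer passed with the block and 8 newly passed; of the lists that passed, all 99 tested with it kept their call. In nuclear input RNA the interferon and NF-kB lists newly passed with it (adjusted p = 0.04975 each, but adjusted p = 0.68 each with an estimated correlation). No paired analysis was possible because the numbers of the synchronised knockdown columns are not the replicate numbers of the labels, and so pair no library with a control.

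Synchronised LINC00704 knockdown gave 2 genes, and 1 with no filter, 1 with limma-voom, 4 with the length trend removed and 1 without column 1 of S2 and S4. MIAT gave 727, and 1577 with no filter and 469 with RPKM of at least 1. Asynchronous LINC00704 knockdown gave 5, and 1 with a pseudocount of 1, 9 with 0.1, 0 with no filter (1929 unadjusted), 1 with RPKM of at least 1, 1 with quantile normalization, 1 with no mean trend and 14 with the length trend removed. Asynchronous LUCAT1 knockdown gave 20, and 0 with a pseudocount of 1, with RPKM of at least 1 and with quantile normalization (2102, 1639 and 1370 unadjusted), 37 with a pseudocount of 0.1, 48 with no filter, 45 with median scaling and 98 with the length trend removed. Without 1 library each, synchronised LINC00704, LUCAT1 and MIAT knockdown ranged over 1 to 1037, 1458 to 3779 and 393 to 986, and their differences between points over 0 to 0. Asynchronous ones ranged over 0 to 39, 0 to 4596 and 1616 to 4652, and control cells among points over 12 to 33 (40 with all libraries) in the LUCAT1 table. With the same controls there were 47 in the MIAT table and 0 in the LINC00704 table with limma (478 unadjusted), and S6 against S0 gave 95 and 7, against 86. A lone library left in a group is assumed to vary like the others. Splitting the controls moved the correlation between knockdowns from 0.73 to 0.24 and 0.30 (LINC00704 and LUCAT1), from 0.59 to 0.0279 and 0.204 (LINC00704 and MIAT) and from 0.70 to 0.34 and 0.44 (LUCAT1 and MIAT).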

Other observations

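The fit of the 10 window libraries alone with the replicate number as a block, and the test of a carry-over of mimosine, were chosen after the results were seen. In that fit 26 genes differed among the windows in whole-cell nascent RNA, 15 of them highest at T0-2 and 5 at T8-10. The gene of cyclin E2, CCNE2, which acts at entry into S phase, was at 5.11 RPKM at T0-2 and 0.749 at T8-10 (limma adjusted p = 0.011). FBXO32, a ubiquitin ligase gene, went from 3.46 to 15.5 RPKM (adjusted p = 0.039). The linker histone gene HIST1H1D was at 6.52, 43.8, 76.4, 53.4 and 19.3 RPKM from the first window to the last, highest at T4-6 (adjusted p = 0.039), and HES1, a Notch target, at 9.22 RPKM at T0-2 and 1.54 at T2-4 (adjusted p = 0.039).

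Whole-cell input RNA had 320 such genes, 144 highest at T0-2 and 93 at T8-10, with 15 of 46 histone genes, 13 of 29 hypoxia and iron genes, 10 of 46 G1/S genes and 9 of 24 immediate early genes. SPRY4, an antagonist of growth factor signalling, was at 5.55 RPKM at T0-2 and 0.692 at T8-10 (adjusted p = 6.0e-04), and HBEGF, a growth factor gene, at 12.2 and 2.13 RPKM (adjusted p = 0.0020). Nuclear input RNA had 1509, 600 highest at T8-10 and 379 at T0-2, with 39 of 44 histone genes, 23 of 45 G2/M genes and 15 of 27 hypoxia and iron genes. Nuclear nascent RNA had 0 in this fit with limma (852 at an unadjusted p under 0.05) and 1 without the block.

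A hypothesis for the hypoxia and iron genes is carry-over of mimosine, which binds iron. Their median difference from asynchronous cells was 1.38, 1.75, 1.28 and 0.97 at T0-2 in whole-cell nascent, whole-cell input, nuclear nascent and nuclear input RNA, and 0.17, 0.53, 0.64 and 0.54 at T8-10. The decline may come from washout of the drug or from progress through S phase, which cannot be told apart because both follow the time since release. The p53 list had 0.80, 0.96, 1.16 and 0.97 at T8-10, against 0.54, 1.12, 0.72 and 0.60 at T0-2.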
